A study of Rattus norvegicus with 23 samples.

How the data were processed

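RNA was sequenced from lung pieces of male rats that had breathed filtered air, a low concentration or a high concentration of eucalyptus wood smoke. Per the labels, 24 rats were randomized, with 8 planned per group, and the smoke chambers were run to a target carbon monoxide concentration of 10 ppm or 20 ppm. The exposure schedule was 4 days in week 1, a break of 3 days and 3 days in week 2. Total RNA came from about 35 mg of tissue with an RNA integrity number of at least 9.0, and 1 µg went into PrepX libraries sequenced on a NextSeq 500.

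The authors aligned the reads with STAR 2.7.3a to the rat genome build rn6, counted and normalized them in Partek with DESeq2, and deposited 1 table whose unit is signal: gene counts divided by a size factor per library. The table holds 19249 genes by symbol and 22 libraries, 7 from air, 8 from low smoke and 7 from high smoke. The labels list 23 samples. The high smoke sample numbered replicate 8, whose label marks it as dropped for quality, had no column and was not analysed here. The counts were fractional in part: only 80.9% to 82.9% of the values under 200 reads lay within 0.02 reads of a whole number of reads, for a reason that was not tested. Whole read counts were not recovered, and count models were not used here. Dividing each library total by its value of 1 read gave 8484131 to 12055512 read equivalents per library. The depth limits the precision of genes with low values most, and no interval for counting error was computed.

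All values were transformed to log2(value + 1), which makes fold changes of genes with low values too small. Genes with a mean of at least 10 over the 22 libraries were tested, which left 14414. A single linear model with the 3 groups was fitted with limma 3.58.1 (intensity trend on, robust off) in R 4.3.3, with contrasts for high smoke against air, low smoke against air, high smoke against low smoke, and a slope over the ordered groups. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over the 14414 genes, and genes with an adjusted p below 0.05 are said to have risen or fallen. No paired analysis was possible because the replicate numbers are only names given in label order.

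For gene groups, 63 lists covering pathways, lung cell types and RNA quality were fixed before the data were examined. Of their 1150 genes, 1018 were found by symbol, 16 by an older or alternative symbol, and 116 were unmatched. The 57 lists with at least 5 genes tested went through limma's camera with its preset correlation of 0.01, adjusted over the lists of each contrast. Each list was also tested with a correlation estimated from its own genes and with ranks, and its members were also adjusted over the list alone. Comparisons of library means used exact two-sided permutation tests, and the per-gene rank test was an exact two-sided Wilcoxon rank-sum test on the 2 groups compared.

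The naming rule, also fixed before the data were examined, took the 10 largest rises and the 10 largest falls in high smoke against air. It did the same in low smoke against air if at least 5 genes passed. Genes had to be past the threshold, with a mean of at least 50 in 1 of the groups and a symbol not starting with LOC, RGD, AABR or ENSRNOG. Clone-based names starting with AC were not excluded. With fewer than 5 genes past the threshold, the 10 genes with the smallest p were named instead and are given as values. High smoke against low smoke was treated the same way with 5 and 5. The rule added the 4 members with the smallest p from each list called in a contrast, and the 2 such members past the threshold from each other list that does not mark a cell type or RNA quality. It also added 8 sentinel genes induced by combustion products. The genes named outside this rule were chosen after their values were seen, and are marked as such. A few genes that the rule selects are not reported here.

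The model was tested on simulated data with the same group labels, known changes and genes drawn independently of each other. At these group sizes it recovered 67% of 1.5-fold and 89% of 2-fold changes for high smoke against air, 62.6% and 93.9% for low smoke against air, and 65% and 90.9% for high smoke against low smoke. Camera called the changed set in 10 of 10 draws, and 3.2% of the unchanged sets had a p below 0.05. Genes in these simulated sets were not correlated, so the share does not measure the error rate of camera for correlated lists.

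The alternatives chosen before the data were examined were other pseudocounts, other level filters, 3 other scalings, array weights, robust variance shrinkage, a fit of only the 2 groups compared, the rank-sum test, other settings of camera, and leaving out each library in turn. After the data were seen, 4 more were added: leaving out the 3 high smoke libraries that stood apart on the first principal component, removing a trend along gene span, every choice of 4 high smoke libraries, and the level of small nucleolar RNA as a covariate. Small nucleolar RNA rows were taken as a list after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.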

Results

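Lung RNA was sequenced from 22 male rats, 7 that breathed filtered air, 8 that breathed low eucalyptus smoke and 7 that breathed high eucalyptus smoke over 2 weeks. The values are normalized counts, and depth was 9636852 ± 1150403 read equivalents in air (SD, n = 7), 10065126 ± 497068 in low smoke (SD, n = 8) and 10460697 ± 969784 in high smoke (SD, n = 7). S100a6, which encodes a calcium-binding protein, took 0.982% ± 0.35 of all counts in air, 1.553% ± 0.426 in low smoke and 2.164% ± 0.578 in high smoke (SD). The first principal component carried 19.7% of the variance. High smoke replicates 1, 3 and 7 scored 51.5, 41.7 and 36.5 on it, the other 4 high smoke libraries 0.3 to 8.8, low smoke libraries -12.7 to -1.8 and air libraries -21.6 to -0.3. Those 3 libraries stood apart from the rest of their group, and values without them are given beside the gene groups below. On the second component, which carried 9.1% of the variance, air replicate 3 scored 44.6 and no other library above 16.

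**Figure D1:**
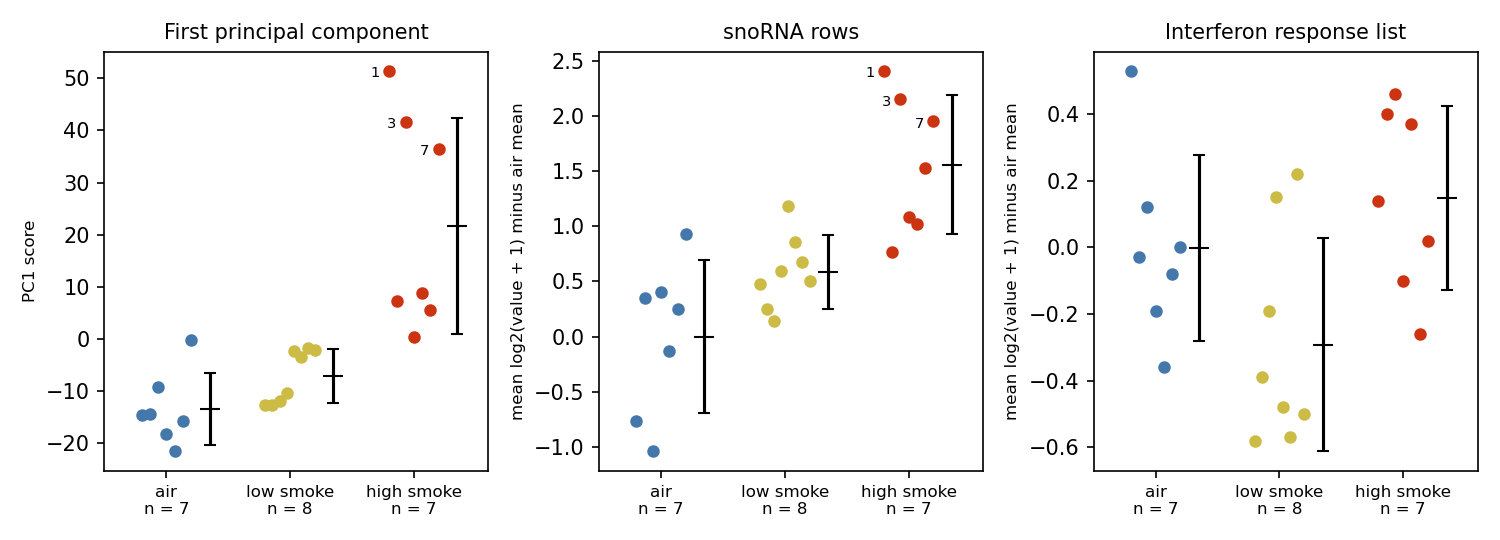
Each point is 1 library: its score on the first principal component, its mean log2(value + 1) over 46 small nucleolar RNA rows minus the air mean, and its mean over the 32 interferon response genes minus the air mean, for air (n = 7), low smoke (n = 8) and high smoke (n = 7), with bars for mean and SD. High smoke replicates 1, 3 and 7, numbered in the plot, score 36.5 to 51.5 on the component, while no other library scores above 8.8.

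High smoke was compared with air to find which lung genes differ after repeated exposure to the higher concentration. Small nucleolar RNAs, which guide chemical modification of ribosomal RNA, rose as a class, together with 8 of 16 antigen presentation genes and single members of the antioxidant, surfactant and respiratory chain groups. The antigen presentation list was called at the preset correlation of camera, with adjusted p = 0.974 with an estimated correlation. Gpx4, the peroxidase that reduces lipid hydroperoxides, rose 1.82-fold from 498 ± 90.8 to 903 ± 151 (SD, n = 7 each, adjusted p = 0.000211). Cat, which breaks down hydrogen peroxide, rose 1.64-fold from 1692 ± 206 to 2820 ± 663 (SD, n = 7 each, adjusted p = 0.000512). RT1-DMb, a chain of the class II molecule that loads peptides, rose 2.08-fold from 95.8 ± 18.7 to 204 ± 56 (SD, n = 7 each, adjusted p = 0.000326). Hsd17b7, an enzyme of cholesterol synthesis, fell by 0.79 on the log2 scale from 116 ± 20.5 to 67.9 ± 19.4 (SD, n = 7 each, adjusted p = 0.00199).

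Of 46 small nucleolar RNA rows, 38 rose (82.6%), 8 did not pass the test and 45 lay above air, while 9% of the other genes rose (two-sided Fisher's exact p = 3.3e-32, over rows that are not independent). This list was taken after the data were seen, and 43 of its rows rose when adjusted over the list alone. Their median change was 1.54 on the log2 scale (2.91-fold), and the library means differed by 1.56 (SE 0.35, exact permutation p = 0.00117, n = 7 each). With an estimated correlation the unadjusted camera p = 0.0233. Snord66 (chromosome 11, 83915892 to 83915967 in build rn6) rose 7.98-fold from 701 ± 396 to 5560 ± 2827 (SD, n = 7 each). SNORD82 rose 7.13-fold, Gm23650 6.84-fold, Snord92 6.64-fold, SNORD58 5.76-fold, SNORD18 5.37-fold and Snord57 4.54-fold. Without high smoke replicates 1, 3 and 7 the median was 1.16 and 12 of 41 rows rose, all 7 of these named rows among them. The larger rises of AC094246.1 (28.15-fold), AC097037.2 (20.44-fold) and AC133270.1 (8.08-fold) belong to unnamed loci, of which AC097037.2 is a processed pseudogene near 0 in air. Its air values went down to 6.81e-07, far below 1 read, which points to reads divided with other loci there. How far that division made its rise was not tested. With those 3 libraries left out AC094246.1 (4.32 on the log2 scale) was still past the threshold and AC133270.1 (2.33) was not, and AC097037.2, which had 281.8, 134.6 and 301.3 in the 3 and at most 38.7 in the other 4, was not tested.

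Antigen presentation genes rose as a list (camera adjusted p = 0.000705), with 8 of 16 members up, 0 down and 8 not past the limma test, or 10 up when adjusted over the list alone. Its adjusted p = 0.974 with an estimated correlation. Beside RT1-DMb, Tapbp, which bridges class I molecules to the peptide transporter, rose 1.29-fold, Tap2, a subunit of that transporter, 1.28-fold, and RT1-Bb, a class II chain, 1.43-fold. B cell markers, from cells that carry class II molecules, had 2 of 13 up, 0 down and a median of 0.32, without a call as a list (camera adjusted p = 0.15, or adjusted p = 0.974 with an estimated correlation). RT1 genes are closely related copies, so reads may be shared among them. With high smoke replicates 1, 3 and 7 left out, the list was still called at the preset correlation, RT1-DMb (0.75 on the log2 scale) and Tapbp (0.38) were still past the threshold, and Tap2 (0.35) and RT1-Bb (0.33) were not.

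Nuclear genes of oxidative phosphorylation were called upward as a list (camera adjusted p = 0.0496), with 8 of 32 members up, 1 down and 23 not past the test, or 9 up and 1 down when adjusted over the list alone. Its adjusted p = 0.974 with an estimated correlation and 0.103 with ranks, and the call ended without any 1 of air replicates 2, 4, 5 and 6, low smoke replicates 1, 2, 3, 6 and 8 and high smoke replicate 7 (adjusted p up to 0.122 without air replicate 4), and without high smoke replicates 1, 3 and 7 together (0.125). Uqcrc2, a core protein of complex III, rose 1.48-fold, Atp5f1a and Atp5f1b, catalytic subunits of ATP synthase, 1.35-fold and 1.32-fold, and Cox5a of complex IV 1.52-fold. Transcripts of the mitochondrial genome went the other way as a list (camera adjusted p = 0.0109), with 5 of 13 members down, 0 up and 8 not past the test, or 6 down when adjusted over the list alone. That list was fixed as a marker of RNA quality, and its adjusted p = 0.974 with an estimated correlation and 0.0523 without air replicate 7. Mt-atp6, an ATP synthase subunit, fell by 1.02 on the log2 scale from 7921 ± 1766 to 4123 ± 1663 (SD, n = 7 each), Mt-nd2 fell by 0.95, Mt-atp8 fell by 0.63 and Mt-nd4 fell by 0.61. Mt-co2 stood at 0.53, short of the threshold. In the fit without high smoke replicates 1, 3 and 7, Uqcrc2 (0.38) and Atp5f1a (0.30) were still past the threshold, and Cox5a (0.41), Atp5f1b (0.31), Mt-atp6 (-0.59), Mt-nd2 (-0.53), Mt-atp8 (-0.49) and Mt-nd4 (-0.30) were not.

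Other lists were not called, and their members are given as counts with the most significant ones. Among antioxidant enzymes 6 of 17 rose and 0 fell, with Gpx4 and Cat leading. Among NRF2 targets, genes of the oxidant-responsive transcription factor, 5 of 27 rose and 2 fell: Fth1, the ferritin heavy chain, rose 1.83-fold and Gsta1, a glutathione transferase, 1.67-fold. Among surfactant genes 4 of 10 rose and 1 fell, with rises of 1.76-fold in Napsa and 1.51-fold in Ctsh, both proteases that process surfactant protein precursors. Cholesterol synthesis had 6 of 23 members down and 0 up, and Insig1, which holds back the sterol-responsive transcription factors, fell by 0.39 on the log2 scale. The unfolded protein response list had 4 of 23 up and 1 down, the latter being Edem1, which targets misfolded glycoproteins for removal (-0.45). In the DNA damage list 3 of 17 rose, among them Phlda3 (1.46-fold) and Sesn2 (1.31-fold), both p53 targets. Heat shock proteins had 3 of 16 up and 1 down, with Cryab, a small chaperone, up 1.66-fold and Hspb8 1.3-fold. Hbb (1.87-fold) and Hba-a2 (1.62-fold), globins carried by red cells and read from similar copies, were the 2 that rose of 14 heme and globin genes. Of the genes just named and in the opening, Gpx4 (0.70), Cat (0.46), Gsta1 (0.49), Napsa (0.49) and Hsd17b7 (-0.75) were still past the threshold without high smoke replicates 1, 3 and 7, and the other genes named in this paragraph were not.

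Chia, an acidic chitinase of type 2 immunity, rose 1.96-fold and was the 1 member of 10 past the test in its list. Cyp2e1 rose 1.92-fold and Ces1d by 0.33 on the log2 scale among 17 xenobiotic enzymes, of which 3 rose and 1 fell. Serpina1, the inhibitor of neutrophil elastase, rose 1.55-fold and the protease Ctsl 1.39-fold among 17 protease genes, of which 3 rose and 1 fell while the list median (-0.03) and mean (0.04) differed in sign. Ptgs1, a cyclooxygenase, fell by 0.51 on the log2 scale and was the 1 of 12 prostaglandin genes past the test. Pnp (1.55-fold) and Gart (1.17-fold) of purine metabolism rose in a list of 23 with 5 up, 3 down, a median of -0.05 and a mean of 0.01. Lpcat3 (1.37-fold) and Pisd (1.22-fold), enzymes of phospholipid remodelling and synthesis, rose in a list of 22 with 3 up and 2 down. Elovl1, which lengthens fatty acids, rose 1.2-fold and Me1, which makes NADPH for lipid synthesis, fell by 0.44, among 22 lipid synthesis genes with 3 up and 2 down. Bcat2 (1.38-fold) and Got2 (1.33-fold) rose among 27 amino acid genes with 4 up and 1 down. Pfkl (1.32-fold) and Pgam1 (1.2-fold) were 2 of the 3 glycolysis genes of 19 that rose. Pgk1 rose by 0.33 on the log2 scale and the demethylase Kdm3a fell by 0.22 among 25 hypoxia targets with 2 up and 1 down. Among 17 clock genes 2 rose and 1 fell, with Cry2 up 1.31-fold. The receptors Aplnr (1.27-fold) and Agtr1a (1.17-fold) were the 2 that rose of 17 vascular genes. Fth1 was also the 1 riser of 7 metal handling genes. Of the genes named in this paragraph only Lpcat3 (0.46) was still past the threshold once high smoke replicates 1, 3 and 7 were left out, and Chia (0.77), Cyp2e1 (0.67), Serpina1 (0.59) and the others were not.

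The other large falls were C4a, a complement component with the close copy C4b (-0.97), the small RNA Gm27820 (-0.92), Fam183a (-0.85), Cnst, a protein of connexin transport (-0.85), Rpl36al, a ribosomal protein with processed copies (-0.84), Ghitm of the inner mitochondrial membrane (-0.84), the secreted protein Fam3b (-0.83) and Wwtr1, the Hippo pathway coactivator TAZ (-0.83). None of these 8 was still past the threshold with high smoke replicates 1, 3 and 7 left out (-0.63 to -0.43). In all, limma called 2343 of 14414 genes, 1327 up and 1016 down, with a median size of 0.41 on the log2 scale and 117 over 2-fold (100 up, 17 down). At an unadjusted p below 0.05 there were 4428 genes, against 721 expected by chance, and the rank-sum test called 746. Without high smoke replicates 1, 3 and 7, 124 genes were called, 121 of them among the 2343, and all 2332 of the 2343 that were still tested kept their sign. Of the 67 rule-named genes called, 18 of the 66 with a value were then still called and all 66 kept their direction. Signs kept in this fit are no independent support, because its libraries also took part in the calls. With each library scaled to the same total, 894 genes rose and 1797 fell, so the balance of up and down depends on the scaling. Leaving out 1 library moved the count by more than 1.5 times for high smoke replicates 1 (1453), 3 (1461) and 7 (1550).

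**Figure D2:**
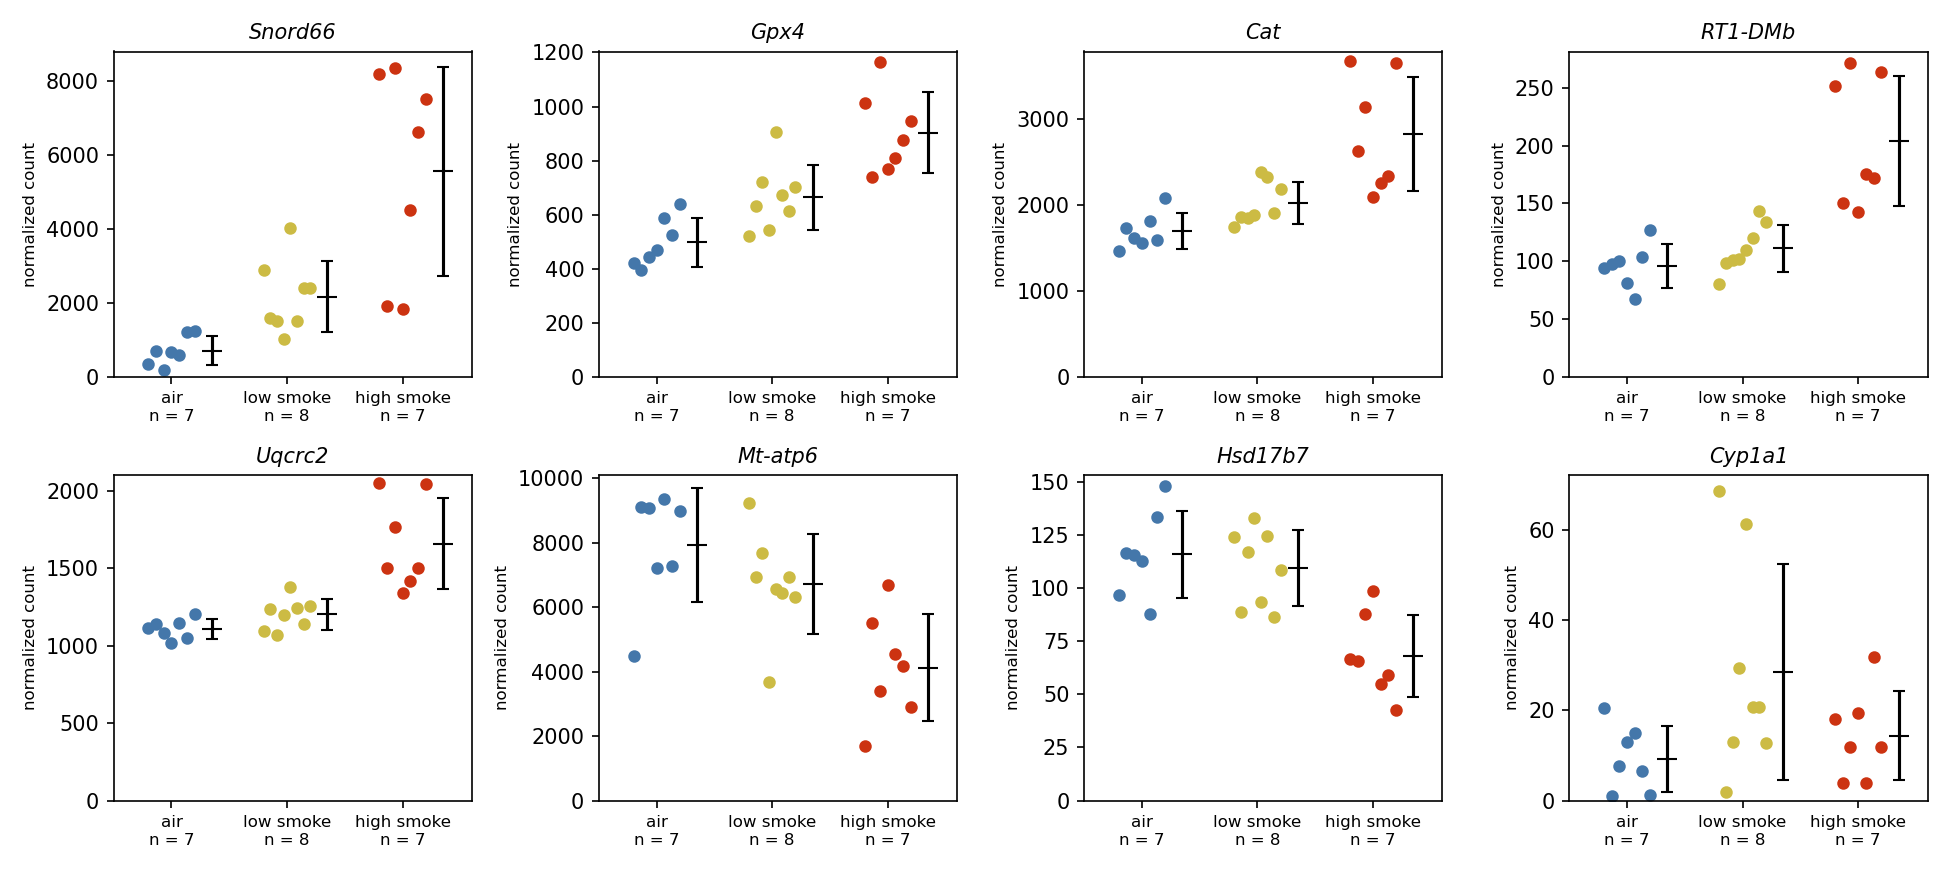
Normalized counts of 8 genes in each library of air (n = 7), low smoke (n = 8) and high smoke (n = 7), on linear axes from 0, with bars for mean and SD. Snord66, Gpx4, Cat, RT1-DMb and Uqcrc2 are higher in all 7 high smoke libraries than in any air library, while Mt-atp6, Hsd17b7 and Cyp1a1 overlap between groups.

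Genes induced by combustion products were followed in every group, whatever their result. None of the 6 sentinel genes tested passed the limma threshold in any comparison, with 0 called, 1 at an unadjusted p below 0.05 in high smoke (Nqo1) and 1 in low smoke (Cyp1a1). Cyp1a1, the monooxygenase induced through the aryl hydrocarbon receptor, was 9.27 ± 7.28 in air (SD, n = 7), 28.6 ± 24 in low smoke (SD, n = 8) and 14.4 ± 9.79 in high smoke (SD, n = 7). Its change in low smoke was 1.46 on the log2 scale (SE 0.61, limma adjusted p = 0.724, or 0.14 over the sentinels alone). Nqo1, a quinone reductase under NRF2, stood at 0.27 in high smoke (SE 0.12, limma adjusted p = 0.115, or 0.176 over the sentinels alone), and passed without air replicate 3 (0.33, adjusted p = 0.0432). Hmox1, which degrades heme, was 421 ± 436 in air (SD, n = 7), a spread set by 1395 in air replicate 3, and 286 ± 40.7 in high smoke (SD, n = 7). Cyp1b1 stood at -0.14, Tiparp at -0.11 and Gclc, of glutathione synthesis, at -0.03 in high smoke against air. Ahrr had a mean of 6.17 and fell below the level filter, and Srxn1 was not analysed here.

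Low smoke was compared with air to ask the same question at the lower concentration. Small nucleolar RNAs had higher values in low smoke, without passing the test: Snord66 stood at 2166 ± 965 in low smoke (SD, n = 8) against 701 ± 396 in air (SD, n = 7), a log2 difference of 1.75, SNORD82 at 1.46 and Gm23650 at 1.42. Aplnr, the receptor for apelin on endothelium, stood at 0.33 and was higher in 8 of 8 low smoke libraries than in any air library, and the kinase Araf stood at -0.24 and was lower in 8 of 8. Interferon response genes were lower as a list, with 30 of 32 members below air and a median of -0.28, a call that was lost with an estimated correlation (adjusted p = 0.928) while the exact permutation test of the library means gave p = 0.0858 (n = 7 and 8). None of these single genes passed the test. Other genes among the 10 with the smallest p were the phosphatase Dusp22 (-0.31), St7l (-0.49), the kinase Pak2 (0.65) and Fam171a1 (0.40), and the adjusted p of the 10 was 0.451 or 0.462. The library means of small nucleolar RNA differed by 0.58 (SE 0.29, exact permutation p = 0.0513, n = 7 and 8), and 8 of 46 rows passed when adjusted over the list alone.

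By camera 10 lists were called in low smoke, though 0 of their members passed limma over all genes. For each of the 10 lists the adjusted p = 0.928 with an estimated correlation. The interferon response list (adjusted p = 5.8e-08) had Usp18 at -0.58, Irf7 at -0.72, Rsad2 at -0.42 and Herc6 at -0.38, and its library mean was below the air mean in 6 of 8 libraries. Immediate early genes, transcribed within minutes of a stimulus, were lower (adjusted p = 3.1e-05, 19 of 27 below air), with Egr1 at -0.70, Nr4a1 at -0.53, Junb at -0.51 and Zfp36 at -0.41. Air replicates 3, 4 and 5 carried that difference, with list means of 0.307, 0.485 and 0.328 against the air mean. Air replicates 1, 2, 6 and 7 stood at -0.383 to -0.218, within the low smoke range of -0.412 to -0.09. Acute inflammation genes were lower (adjusted p = 0.00223, 18 of 19 below air), with Cxcl2 at -0.83, Ccl2 at -0.56, Selp at -0.51 and Ptgs2 at -0.47. Glucocorticoid targets were lower (adjusted p = 0.00482, 15 of 17 below air), with Hif3a at -0.64, Dusp1 at -0.57, Ddit4 at -0.35 and Klf9 at -0.19. Cardiac muscle markers, which a lung piece can hold in the walls of pulmonary veins, were lower (adjusted p = 0.00234, 13 of 13 below air), with Myl4 at -1.62, Myl7 at -1.36, Mybpc3 at -1.18 and Myom2 at -0.95. Markers of alveolar type 1 cells were higher (adjusted p = 0.00961), with Ager at 0.43, Scnn1g at 0.28, Pdpn at 0.27 and Rtkn2 at 0.20. Endothelial markers were higher (adjusted p = 0.00795), with Gpihbp1 at 0.65, Plvap at 0.30 and Sox18 at 0.29 beside Aplnr, the 1 member past the test when adjusted over the list alone. Apart from the estimated correlation, the highest camera adjusted p of the endothelial list over the alternatives was 0.0527, short of a call. Extracellular matrix genes were higher (adjusted p = 0.0118), with Fbn1 at 0.35, Col4a2 at 0.22, Col5a1 at 0.20 and Sparc at 0.19. The lists for RNA quality also moved: mitochondrial transcripts were lower (adjusted p = 0.025), with Mt-nd3 at -0.30, Mt-nd2 at -0.25, Mt-atp8 at -0.23 and Mt-co1 at -0.17, and so were ribosomal proteins (adjusted p = 0.0104), with Rpl12 at -0.61, Rps29 at -0.37, Rpl5 at -0.24 and Rps6 at 0.23. Leaving out 1 library ended the call for mitochondrial transcripts (air replicates 2, 3 and 7 and low smoke replicates 2, 4 and 6, adjusted p up to 0.261), extracellular matrix (air 1, 5 and 7 and low smoke 5 and 6, up to 0.342), type 1 cells (air 1 and low smoke 3, up to 0.0572), ribosomal proteins (air 3 and 7, up to 0.544), acute inflammation (air 3, 0.0657), cardiac muscle (air 6, 0.23) and glucocorticoid targets (air 5, 0.116).

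For single genes in low smoke against air, limma called 0, with 923 at an unadjusted p below 0.05 against 721 expected by chance and a smallest adjusted p of 0.451, and the rank-sum test called 0 with 908 unadjusted. Without air replicate 5 limma called 2 genes.

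**Figure D3:**
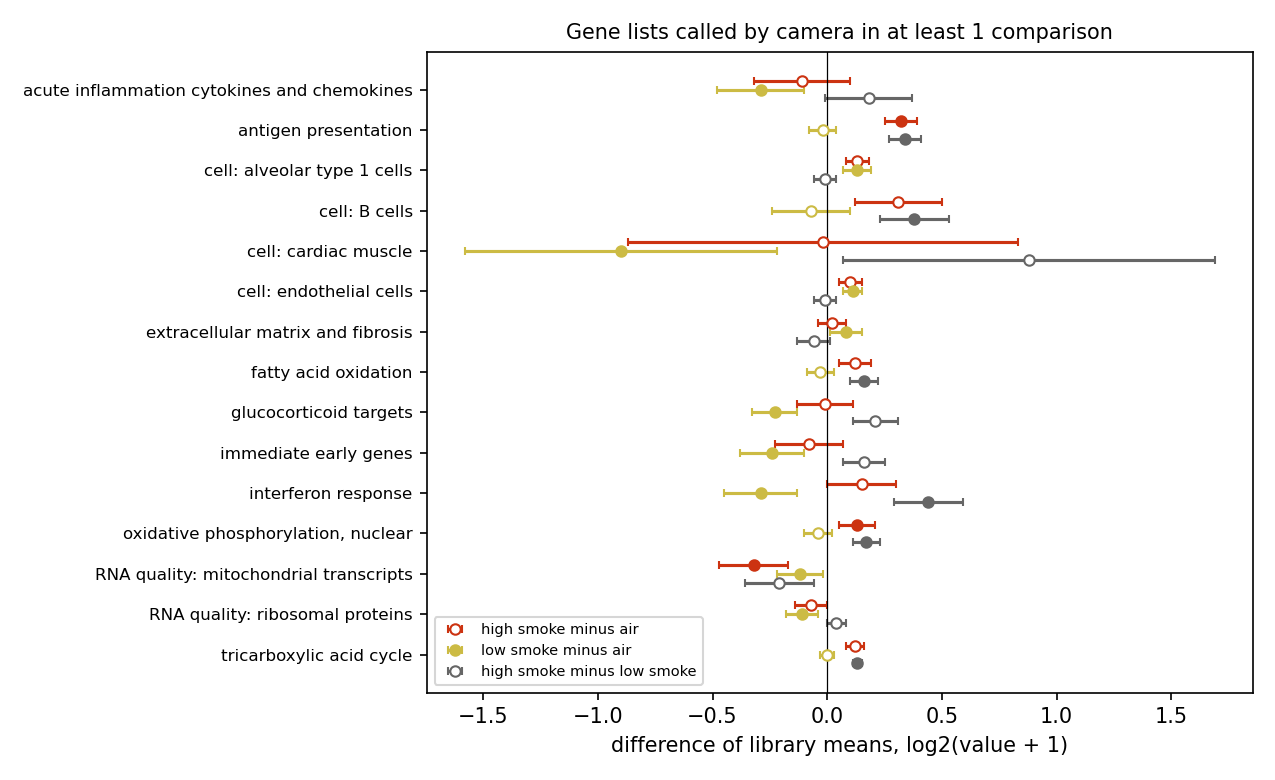
Difference of library means in log2(value + 1) with its SE for each gene list that camera called in at least 1 comparison, with filled points where it was called at the preset correlation. Interferon response genes lie at -0.29 in low smoke minus air and at 0.44 in high smoke minus low smoke.

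High smoke was compared with low smoke to separate the concentrations. Interferon response and antigen presentation genes were higher at the higher concentration, together with nuclear respiratory chain and tricarboxylic acid cycle genes, at the preset correlation of camera. With an estimated correlation none of these 4 lists was called (adjusted p = 0.843, 0.761, 0.843 and 0.843). Irf1, a transcription factor of the interferon response, rose 1.32-fold from 1135 ± 92.8 (SD, n = 8) to 1502 ± 140 (SD, n = 7, limma adjusted p = 0.014). B2m, the light chain of class I molecules, rose 1.44-fold from 20310 ± 2207 (SD, n = 8) to 29940 ± 8167 (SD, n = 7, limma adjusted p = 0.022). Mdh1, the cytosolic malate dehydrogenase, rose 1.37-fold from 3616 ± 142 (SD, n = 8) to 5081 ± 1258 (SD, n = 7, limma adjusted p = 0.0228). Of the 55 rule-named genes called in this comparison, 0 of the 54 with a value were past the threshold after high smoke replicates 1, 3 and 7 were left out, and all 54 kept their direction, with Irf1 at 0.35, B2m at 0.23 and Mdh1 at 0.19. The remaining libraries also took part in the calls, so the kept directions are no independent support.

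In the interferon list (camera adjusted p = 4.5e-07) 5 of 32 members rose, 0 fell and 27 did not pass, or 13 rose when adjusted over the list alone, and its adjusted p = 0.843 with an estimated correlation. Isg15 rose 1.78-fold, Usp18 1.78-fold and Rtp4 1.72-fold. The library means of the list differed by 0.44 (exact permutation p = 0.0183, adjusted over 3 comparisons 0.055, n = 8 and 7). Between high smoke and air they differed by 0.15 (exact permutation p = 0.339, n = 7 each), with 1 of 32 members up and no call as a list (camera adjusted p = 0.359), so much of the gap to low smoke lies in the lower values of low smoke. In the antigen presentation list (camera adjusted p = 9.9e-07) 7 of 16 rose, or 13 when adjusted over the list alone, and its adjusted p = 0.761 with an estimated correlation. RT1-DMb rose 1.80-fold, RT1-Bb 1.39-fold and Tapbp 1.2-fold. In the fit with the other 4 high smoke libraries Isg15 stood at 0.63, Usp18 at 0.69, Rtp4 at 0.66, RT1-DMb at 0.54, RT1-Bb at 0.29 and Tapbp at 0.27, none past the threshold. Nuclear genes of oxidative phosphorylation (camera adjusted p = 0.00029, or adjusted p = 0.843 with an estimated correlation) had 8 of 32 up and 0 down, or 12 up and 1 down when adjusted over the list alone. Ndufb8 rose 1.56-fold, Uqcrc2 1.37-fold, Ndufv2 1.3-fold and Atp5f1a 1.26-fold, and with the other 4 high smoke libraries they stood at 0.32, 0.26, 0.27 and 0.20, short of the threshold. Mitochondrial transcripts, the marker of RNA quality, lay the other way with 4 of 13 down, 0 up and a median of -0.20, without a call as a list (camera adjusted p = 0.0669, or adjusted p = 0.892 with an estimated correlation). The tricarboxylic acid cycle list (camera adjusted p = 0.033, or adjusted p = 0.843 with an estimated correlation) had 4 of 22 up, or 8 up and 1 down when adjusted over the list alone, with Fh up 1.43-fold, Sdhd 1.26-fold and Sdhc by 0.32 on the log2 scale beside Mdh1 (0.29, 0.24 and 0.21 with the other 4 high smoke libraries, short of the threshold). Fatty acid oxidation genes (camera adjusted p = 0.0158, or adjusted p = 0.843 with an estimated correlation) had 1 of 26 up, or 3 when adjusted over the list alone, and Eci1 (0.32), Acadm (0.26) and Ehhadh (0.26) did not pass over all genes. The fatty acid oxidation call ended without high smoke replicate 7 (adjusted p = 0.0518), and that of the tricarboxylic acid cycle without high smoke replicate 2, 4 or 7 (up to 0.0675 without replicate 2) and with ranks (adjusted p = 0.0942). B cell markers (camera adjusted p = 0.0129, or adjusted p = 0.843 with an estimated correlation) lay above low smoke in 13 of 13 members, 0 of which passed limma over all genes or over the list alone, with Cd79a at 0.65, Cd79b at 0.63, Blk at 0.47 and Fcer2 at 0.42. Apart from the estimated correlation, the highest camera adjusted p of the B cell list over the alternatives was 0.0704, short of a call.

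Of 46 small nucleolar RNA rows 20 rose and 0 fell between low and high smoke, with a median of 1.07 and library means that differed by 0.97 (SE 0.26, exact permutation p = 0.00187, n = 8 and 7). The count of 20 was 0 without any 1 of high smoke replicates 1, 3 and 7 (medians of 0.90, 0.97 and 0.98), 5 without low smoke replicate 2 and 9 or 10 without low smoke replicate 1, 3 or 4, 12 with the gene span trend removed, and 31 without high smoke replicate 2. With all 3 of those high smoke libraries left out the median was 0.55 and 0 of 41 rows rose. SNORD82 rose 2.59-fold, Gm23650 2.56-fold and Snord92 2.52-fold, and the unnamed AC097037.2 and AC094246.1 rose 22.29-fold and 5.95-fold. Falls were led by Cntn1, a neural adhesion protein (-0.89), Gm27820 (-0.82), the orphan receptor Gpr158 (-0.82), Mt-atp6 (-0.78) and Fam183a (-0.78). Antioxidant enzymes had 4 of 17 up, with Cat 1.38-fold and Gpx4 1.36-fold. NRF2 targets had 3 of 27 up and 1 down, with Gsta1 1.57-fold and Ephx1 1.28-fold. Stress genes of the unfolded protein response had 3 of 23 up and 1 down, with Atf4 1.31-fold and Herpud1 1.26-fold. Napsa rose 1.54-fold and Ctsh 1.38-fold, the 2 of 10 surfactant genes past the test. Cholesterol synthesis had 3 of 23 down, with Hsd17b7 at -0.71 and Insig1 at -0.34. In other lists Cryab (1.51-fold), Serpina1 (1.45-fold), Ctss (1.31-fold), Chia (1.54-fold), Pnp (1.35-fold), Sesn2 (1.21-fold), Got2 (1.3-fold), Sat1 (1.33-fold), Agpat2 (1.39-fold), Elovl1 (1.17-fold), Bnip3 (1.33-fold), Agtr1a (1.2-fold), Hba-a2 (1.42-fold) and Hbb (1.47-fold) rose. Zmat3 (-0.60), Ptgs1 (-0.44), Gmps (-0.37) and Clock (-0.32) fell. With the other 4 high smoke libraries none of the genes with a value in this paragraph was past the threshold, as for Cat (0.21), Gpx4 (0.29), Gsta1 (0.40), Napsa (0.30), Hsd17b7 (-0.67) and Ptgs1 (-0.13).

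In all, limma called 977 genes between high and low smoke, 548 up and 429 down, with 3690 at an unadjusted p below 0.05 and 183 called by the rank-sum test. With each library scaled to the same total, 414 genes rose and 633 fell, so the balance depends on the scaling here too. Without high smoke replicates 1, 3 and 7, limma called 0 genes, with 939 at an unadjusted p below 0.05. All 973 of the 977 that were still tested kept their sign, which the choice of genes in the same libraries makes likely. All 6 lists were still called then at the preset correlation. Leaving out 1 library moved the count by more than 1.5 times in 9 cases, to 29, 35 and 51 without high smoke replicates 7, 1 and 3, to 316, 296, 550 and 399 without low smoke replicates 1, 2, 3 and 4, and to 1651 and 1575 without high smoke replicates 4 and 6.

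Over the 3 ordered groups, 2228 genes had a slope past the threshold, 1278 upward and 950 downward, and 2210 of them were called in the same direction between high smoke and air. With each library scaled to the same total, 862 slopes were upward and 1741 downward, so this balance depends on the scaling. Without high smoke replicates 1, 3 or 7 the slope count was 1345, 1329 or 1425, and 155 without all 3. Between low and high smoke 792 of the 2343 genes were also called in the same direction. Both contrasts use the same 7 high smoke libraries, so this overlap is partly built in. Without high smoke replicates 1, 3 and 7 there were 0 calls between low and high smoke. In low smoke 89.2% of the 2343 genes had the sign they had in high smoke, but both contrasts share the air libraries: unchanged groups simulated with the same shared air gave 85.1% (66.5% to 96.5%). Across genes, which are not independent replicates, the log2 changes of both smoke groups against air had r = 0.55, against 0.51 (0.30 to 0.67) in those simulations. Their covariance of 0.0345 lay above the simulated 0.0176 (0.01 to 0.0285). With the air libraries split so that each contrast had its own, r had a median of 0.20 over 35 splits. No gene was called by limma in both smoke groups, a count of 0 set by the 0 calls in low smoke, which had 923 at an unadjusted p below 0.05 and 0 by the rank-sum test.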

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

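The tests of gene span, read depth, sequencing sample numbers, library scaling, short RNA recovery and neutrophil markers, and the random splits of the high smoke and air and of the low smoke and air libraries, were chosen after the results they bear on had been seen. The random splits of high against low smoke and of the ordered groups, the host genes and the other 3 tests of the interferon list were chosen before.

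For the 2343 genes called between high smoke and air, 1 of 100 splits drawn from those 14 libraries, the real one, gave as many, and the highest of the others gave 342. This argues against chance but does not exclude it, since 100 splits cannot resolve anything rarer than 1 of 100. The real split was also the only 1 of 100 to give as many for the 977 genes between high and low smoke (the highest other 919). It was so too for the 2228 genes with a slope over the ordered groups (the highest other 3). That slope rests on the air and high smoke means, so its result is no separate support beside the 2343 genes. The split with 919 calls differed from the real one by 1 swap: 6 of its 7 places for high smoke held high smoke libraries, replicates 1, 3 and 7 among them. For the 0 genes called by limma in low smoke (923 at an unadjusted p below 0.05, 0 by the rank-sum test), the splits decide nothing, because every split gives at least 0 (100 of 100, the highest other 210). The sequencing sample numbers fall into 3 unbroken blocks, 1 per group, so library preparation or sequencing order and smoke cannot be told apart in these comparisons.

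High smoke replicates 1, 3 and 7 carried much of the high smoke result: on a score over the called genes they stood at 1.23 to 1.43, the other 4 at 0.49 to 0.70, low smoke at 0.12 to 0.45 and air at -0.14 to 0.23, and 4 libraries gave 124 calls with none of the 3 kept, 447 to 959 with 1, 1414 to 2265 with 2 and 3229 to 3573 with all 3. The score took 1289 risen and 1016 fallen genes called between high smoke and air in these same libraries, without the small nucleolar RNA rows. That choice of genes sets high smoke above air and favours a wide gap for the 3. Removing a trend along gene span left a slope of 0.95 between corrected and original changes of all high smoke libraries against air, so those changes were little altered. That slope does not measure the gap between the 3 libraries and the other 4, so gene span stays open as a cause of the gap. The 3 were the shallowest of their group (-0.18 in mean log2 depth). The slope on depth within air and low smoke predicts a gap of 0.06 (upper 95% bound 0.17) where 0.68 was seen. This argues only weakly against depth as the whole cause. The choice of genes may make the 0.68 too large. It also favours genes with little spread within groups, which may make the 0.06 too small. The score's relation with depth differed in sign between air (r = -0.58) and low smoke (r = 0.17). The sequencing sample numbers of the 3 libraries, 16, 18 and 22 among 16 to 22, form 3 separate runs, which argues against a block of neighbouring sequencing sample numbers. Among high smoke libraries the 3 had the most genes at 0, 6.37% to 7.81% against 4.68% to 5.72% in the other 4. The 10 highest genes of the 3 also took more counts, 7.74% to 8.02% against 6.29% to 7.2%. On the mitochondrial list of RNA quality replicate 1 scored -0.977, the lowest of all libraries. Replicates 3 and 7 (-0.246 and -0.339) lay among the other 4 there. Preparation batches, base composition and transcript length were not tested here. A stronger response of those 3 rats to smoke stays open as an untested biological explanation, which these values do not tell apart from library quality.

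Small nucleolar RNA rows were higher with smoke, by a median of 1.54 in high smoke and 0.57 in low smoke on the log2 scale. The lowest median over 3 other scalings was 1.48, which argues against the scaling of the libraries. For 21 of the 46 rows, 18 host genes on the same strand were found. The hosts had a median of 0.04 (SE 0.08 over genes, 4 up and 1 down) where their small nucleolar RNAs had 1.62. For those rows this argues against a matching rise of the host transcripts, while transcription itself was not measured. Recovery of short RNA in the libraries stays open: other short RNA rows had a median of 0.05, but 9 of those 27 rose and 3 fell, so a median near 0 settles nothing. Rows up to 100 nucleotides had a median of 1.69 (28 rows) and longer ones up to 300 nucleotides 1.29 (11 rows), leaving out 7 rows whose span is longer still. A candidate explanation besides recovery is a change in the processing or stability of these RNAs after smoke, which was not tested.

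Interferon response genes were lower in low smoke than in air, with a median of -0.28 over 32 genes. Chance cannot be excluded, since the exact permutation test of the library means gave p = 0.0858 (adjusted over 3 comparisons 0.129, n = 7 and 8). The call does not hang on 1 library, with a highest adjusted p of 0.000585 over the fits without 1 library, although it is lost with an estimated correlation (adjusted p = 0.928). The median of 72 genes from 5 immune cell lists was -0.05, with an SE of 0.03 over genes, which are not independent. Over libraries the T and NK cell list was -0.04 ± 0.27 in low smoke (SD, n = 8), with an SD of 0.44 in air (n = 7). The B cell list was -0.07 ± 0.25 in low smoke, with an SD of 0.39 in air. With that spread, fewer T, NK and B cells stay open as a cause. The spread was smaller for alveolar macrophages, -0.05 ± 0.08 in low smoke (SD, n = 8) with an SD of 0.16 in air. Interstitial macrophages and monocytes stood at -0.06 ± 0.13, with an SD of 0.14 in air. Dendritic cells stood at -0.05 ± 0.16, with an SD of 0.2 in air. These lists give little sign of fewer macrophages or dendritic cells but do not exclude it. Fewer neutrophils stay open too, since 8 neutrophil markers had a median of -0.24 (SE 0.16 over genes, 6 of 8 below air). So does an effect of low smoke on interferon tone, an untested biological explanation.

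Single libraries stood far from the rest of their group in 30 of 543 group tests, about the 27.2 that chance gives, and these are listed as values. Air replicate 3 held the most of them, 6, and had the lowest array weight (0.41). Its score of 44.6 on the second principal component was not among these tests. Without that library 2726 genes were called between high smoke and air, against 2343 with it. In air replicate 3, AC094246.1 was 2.31 (others 39 to 97.2), Fbn1 1547 (2201 to 2829), Hmox1 1395 (164 to 410.5), Pak2 108 (184 to 252), the ribosomal protein list 0.36 (-0.14 to 0.06) and the tricarboxylic acid cycle list 0.17 (-0.06 to 0.02). In air replicate 5, Cd79b was 34.9 (97.6 to 184), Fcer2 48.9 (77.5 to 109), Ptprcap 48.9 (86.3 to 129.6) and the B cell list -0.85 (0.01 to 0.29). In air replicate 7, Acot8 was 506 (214 to 309.5), Ces1d 12720 (8595 to 9851) and Gmps 374 (486 to 524.5). In air replicate 1, Mt-atp6 was 4469 (7197 to 9366) and Mt-co1 49480 (29060 to 36270). Tapbp was 517 in air replicate 2 (635.5 to 706), and AC097037.2 was 5.1 in air replicate 4 and 2.94 in low smoke replicate 8, with every other library of both groups near 0. In low smoke replicate 1, Fcer2 was 148 (70.7 to 96.4) and Mt-nd4 6747 (4422 to 5255). In low smoke replicate 3, AC094246.1 was 8.999 (166 to 639) and Hbb 2546 (4068 to 6142). Mt-atp6 was 3682 in low smoke replicate 4 (6306 to 9222). In low smoke replicate 5, Phlda3 was 744 (311 to 459) and RT1-Db2 198 (119 to 147). In high smoke replicate 4, Ager was 12360 (15980 to 18340) and Me1 1190 (639 to 835). Fam183a was 66.8 in high smoke replicate 2 (23.7 to 33.9), Tiparp 331.5 in high smoke replicate 5 (399.8 to 447.5) and Zmat3 16.9 in high smoke replicate 1 (28.6 to 41.7).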

How the results depend on the processing

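The alternatives without the 3 high smoke libraries, with the level of small nucleolar RNA as a covariate and with the gene span trend removed were chosen after the data were seen. For genes changed, high smoke against air, the count of 2343 was 124 without high smoke replicates 1, 3 and 7, 1351 with only the 2 groups compared in the fit, 746 by the rank-sum test, 0 with the covariate (1473 at an unadjusted p below 0.05 in limma), where the slope on the original changes of the called genes was 0.49 and the median standard error 1.54 times larger, and 1453 (without high smoke replicate 1) to 2863 (without high smoke replicate 4) over the fits without 1 library. For genes changed, low smoke against air, the 0 of limma (923 unadjusted, 0 by rank-sum) was 1 without the 3 libraries and 0 to 2 without 1 library. For genes changed, high smoke against low smoke, the 977 was 0 without the 3 libraries (939 unadjusted), 0 with the covariate (1759 unadjusted, slope 0.57 over the genes called in high smoke against air), 183 by the rank-sum test, and 29 (without high smoke replicate 7) to 1651 (without high smoke replicate 4) without 1 library. For genes with an ordered trend, air to low to high smoke, the 2228 was 155 without the 3 libraries and 1329 (without high smoke replicate 3) to 2746 (without air replicate 3) without 1 library. Fewer libraries lower the power of these fits, but leaving out the 3 together gave the lowest count of the 35 ways to keep 4 high smoke libraries. With each library scaled to the same total the share of called genes that rose went from 56.6% to 33.2% for high smoke against air, where 2691 genes were called, and the median of all genes moved by less than 0.1. For gene lists called, high smoke against air, the 3 lists were 0 with an estimated correlation, 2 with ranks, with quantile normalization or without the span trend, 5 with no level filter, 5 with the same total and 6 with array weights. For gene lists called, low smoke against air, the 10 were 0 with an estimated correlation, and for gene lists called, high smoke against low smoke, the 6 were 0 with an estimated correlation and 10 with no level filter. The estimated correlation gave the highest adjusted p of each of these 19 list calls. The sentinel genes called were 0 to 1 without 1 library, the 1 being Nqo1 without air replicate 3. A few sentinel values near 0 changed sign. Hmox1, high smoke against air, ran from -0.32 to 0.19 without 1 library and was 0.07 with array weights. Hmox1, low smoke against air, ran from -0.47 to 0.04. Gclc, high smoke against air, ran from -0.07 to 0.02 and was 0.01 without the span trend. Nqo1, low smoke against air, ran from 0 to 0.12. Cyp1b1, high smoke against low smoke, ran from -0.09 to 0.02. Tiparp, high smoke against low smoke, ran from -0.03 to 0.07, and was -0.02 with the same total and -0.02 without the 3 libraries. Of 122 called results of named genes, 53 lost the call without at least 1 library and none changed sign in the alternatives run for them, which reuse the same libraries. With the covariate the changes shrank and their errors grew. Apart from that and the number of libraries in a fit, the cause was not tested. The count models edgeR and DESeq2 were not run because whole reads were not recovered, and high smoke replicate 8 was not included because it has no column. Depth limits genes with low values such as Cyp1a1 most.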

Other observations

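The correlations with small nucleolar RNA and depth, and the genes that follow, protein-coding genes with large changes between high smoke and air, were chosen after the results were seen. Krt8, a keratin of simple epithelium, rose 2.12-fold from 1829 ± 466 to 3860 ± 986 (SD, n = 7 each), and S100a6 rose 2.35-fold from 95280 ± 34680 to 223000 ± 67820 (SD, n = 7 each). Ndufc1, a subunit of respiratory complex I, and Acot8, a peroxisomal thioesterase, each rose 2.39-fold. RT1-Db2, a class II gene with close copies, rose 2.35-fold, Ifit1bl, an interferon-induced gene, 2.33-fold, Psmb4, a proteasome subunit, 2.21-fold, and Rarres2, which encodes the chemoattractant chemerin, 2.24-fold. Lamtor4 (2.31-fold), Ccno of multiciliated cell formation (2.26-fold), the lymphocyte gene Ptprcap (2.1-fold), Letm2 (2.07-fold), Svbp (2.07-fold) and Rpl11, a ribosomal protein with processed copies (2.06-fold), also rose. Rbm27, an RNA-binding protein, fell by 0.81 on the log2 scale from 245 ± 30.6 to 140.5 ± 28.9 (SD, n = 7 each) and was below air in 7 of 7 libraries, and Ccdc50 and Rps15 each fell by 0.81. Without high smoke replicates 1, 3 and 7, 5 of these 17 were still past the threshold: Ndufc1 (1.05), Acot8 (0.89), RT1-Db2 (0.84), Rarres2 (0.76) and Rbm27 (-0.59).

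Cell type markers were not called as lists between high smoke and air. Fibroblast markers had 4 of 18 up and 1 down, interstitial macrophage and monocyte markers 4 of 13 up and 1 down, alveolar type 2 markers 3 of 16 up and 1 down, smooth muscle and pericyte markers 3 of 19 up, and B cell markers 2 of 13 up with 11 above air. Neutrophil markers, with a median of -0.07, had none of 8 past the limma test, and cell cycle genes, with 18 of 24 below air, had none past it. Cardiac muscle markers varied more between rats than between groups, with a mean against air of -0.90 ± 1.25 in low smoke (SD, n = 8), -0.02 ± 1.78 in high smoke (SD, n = 7) and an SD of 1.35 in air (n = 7). Ribosomal protein genes split, with 6 of 29 up and 7 down between high smoke and air.

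Within the air group the score over the called genes, which leaves out small nucleolar RNA rows, and the level of small nucleolar RNA had r = 0.14 (exact permutation p = 0.768, n = 7). Their rho was -0.14 (exact permutation p = 0.782), and r = 0.49 without the 2 libraries farthest from the median. Within low smoke they had r = 0.67 (exact permutation p = 0.0681, adjusted over 6 relations 0.166, n = 8) and rho = 0.64 (exact permutation p = 0.0962), and r = 0.54 without the 2 libraries farthest from the median. With log2 depth the score had r = -0.58 within air (exact permutation p = 0.177, adjusted over 6 relations 0.266, n = 7), rho = -0.61 (exact permutation p = 0.167) and r = -0.59 without the 2 libraries farthest from the median. Within low smoke it had r = 0.17 (exact permutation p = 0.684, adjusted over 6 relations 0.768, n = 8), rho = 0.36 (exact permutation p = 0.389) and r = 0.11 without the 2 farthest. The high smoke libraries fall into clusters of 3 and 4, so no correlation is given within that group. Its replicates 1, 3 and 7 had small nucleolar RNA levels of 1.95 to 2.41 against air and the other 4 had 0.77 to 1.53.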
